A study of Drosophila melanogaster with 2 samples.

How the data were processed

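Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole larvae of Drosophila melanogaster at the wandering stage, males and females together. Per the labels, the larvae carried a stable transgene that encodes Jim, a C2H2 zinc finger transcription factor, with green fluorescent protein (GFP) at its C terminus, and the immunoprecipitation used an antibody against GFP. The samples form 1 group of 2 biological replicates, which the labels number 1 and 3. Per the labels, chromatin was sheared by sonication, and the library size range was 175 to 275 bp for replicate 1 and 200 to 325 bp for replicate 3. The labels name a control experiment, and its values were not used here.

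The deposited files are narrowPeak lists of regions on 2 assemblies of the fly genome, dm6 and dm3. Per the deposited text notes, each replicate list derives from the alignment of that replicate and a control, and the pooled list from both alignments and a control. The IDR list, thresholded on the irreproducible discovery rate, derives from these 3 lists, per the same notes. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list held 30000 regions, and the IDR list held 1476 regions on dm6 and 1470 on dm3. On dm6 all 1476 regions of the IDR list, and on dm3 all 1470, were the strongest regions of the pooled list of that assembly by signal, so the IDR list is a prefix of the pooled list by rank.

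The height of each region is the deposited signal value, on the scale of the authors' caller. The scale differed between lists, with a lowest signal of 20.6 in the pooled list, 10.9 in replicate 1 and 12.4 in replicate 3, so signal was used only for ranks and contrasts within a list. The deposited q-value field of narrowPeak was treated as a score, because 20027 regions of the pooled list held values below 0. It entered no test. The number of reads per library is unknown, so no floor of detection is given. The intervals on numbers, shares and odds of regions or genes cover counting error only, and those on the Spearman correlation and on the log2 signal difference are bootstrap intervals over regions.

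Coordinates are those of dm6, printed from 1, and the arms 2L, 2R, 3L, 3R, 4 and X were analysed, 133.9 Mb in all. All dm6 regions on these 6 arms ended within the arms of the Release 6 reference sequence. Genes came from Ensembl release 115 (BDGP 6.54), with 13945 protein-coding genes among 18164 annotated genes after transposable elements were left out. The dm3 lists were compared only by counts, ranks and overlaps among themselves, and no coordinate was converted. The 1 dm6 region outside the 6 arms, on Y in the list of replicate 3, was left out.

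A summit was called promoter-proximal within 500 bp of any annotated transcription start site (TSS), and distal otherwise. The background for position and chromosome was the 28524 pooled regions outside the IDR list, with 100000 uniform random positions as a second background. An IDR peak counted as found in a replicate when its summit lay in one of the 1476 strongest regions of that replicate. The 26 gene lists hold 411 entries, some of them symbol patterns, of which 7 matched no gene and 7 were matched through an older symbol. For each list, genes with an IDR summit within 500 bp of a TSS were compared with all other protein-coding genes by Fisher's exact test. A gene with more annotated TSSs has more chances to count as bound, and only the alternative with 1 TSS per gene removes this. The 3 noncoding RNA genes that the lists hold, roX1, roX2 and Hsromega, were added to the genes of this test. The 23 preset motifs and all 2080 6-mers, on either strand, were counted in windows of 50 bp to each side of summits and in windows of that size centred 1000 bp to each side, by the same test. All tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within each family, and the threshold was an adjusted p of 0.05. Medians of log2 signal were compared by a permutation test with 100000 resamples. Intervals on shares are exact Clopper-Pearson intervals, those on odds ratios Woolf intervals, and all are at 95%. Regions and genes, not animals, are the units of these tests, so the p values describe these lists and not the spread between larvae. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

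The tests were tried on simulated data. In 50 simulated sets of bound genes without an effect, drawn over 13945 genes, 0 of 1300 list tests passed the threshold. A rise of 3 times planted in a list of 80 genes was called in 43 of 50 runs. Most lists are shorter, and simulated genes were bound independently of their neighbours, so this rate does not carry over to the shorter lists. At 1476 random positions, drawn without regard to promoters, 0 motifs and 0 6-mers passed. A motif planted in 10% of them was called with 0 others. IDR summits lay at promoters more often than random positions did, so these runs give no rate of false calls at IDR summits.

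Lists, motifs, windows, tests and the rule for named genes were fixed before the data were examined. The rule took the 10 IDR peaks of highest signal with the gene of the nearest TSS, jim, the 4 members with the highest IDR peak at a TSS for each list past the threshold and at most 2 for other lists, the 5 protein-coding genes with the most IDR summits in the gene body and 2 kb upstream, the motifs past the threshold, and 10 6-mers, 5 higher and 5 lower. Of the list members that the rule selects, 1 is not reported here. Alternatives changed the TSS window and set, the backgrounds, the windows and flanks, the overlap, the number of regions and the assembly, or used 1 replicate alone. Taking the 1476 strongest regions of the pooled list was also planned, and it is the IDR list itself.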

Results

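The lists describe where GFP-tagged Jim was recovered on chromatin in whole larvae at the end of larval life, in 1 group of 2 biological replicates of unknown read depth. The 1476 IDR peaks on dm6 covered 373447 bp, with a median width of 260 bp, and their deposited signal ran from 65.3 to 529.5 with a median of 85.9. The labels state no purpose beyond mapping the protein, so the comparisons asked how far the 2 replicates shared regions, where the regions lay, which genes they marked and which sequences stood at their summits.

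The strongest IDR peak lay in the gene that encodes the tagged protein itself. It spanned 22822568 to 22822731 on 3L, in an intron of jim (FBgn0027339), 2161 bp from a jim TSS, with a signal of 529.5, and it ranked 1 in replicate 1 and 2 in replicate 3. The jim gene, on the minus strand of 3L from 22789233 to 22835194, held 6 IDR summits with its 2 kb upstream, against 0.529 at the density of the 6 arms. That is 11.3 times the genome density, with an exact Poisson interval of 4.16 to 24.7. Of 11 other protein-coding genes with at least 6 summits, 4 were at least as dense, among them tara at 22.3 times, a comparison made after the values were seen. A second peak lay 3 bp from a jim TSS in the 5 prime UTR (22824702 to 22824961, signal 186.3), and another lay 442 bp from the TSS at the start of the gene (22835506 to 22835765, signal 223.7). The other 3 were intronic, with signals of 84.5, 128.1 and 113.5. Within 20 kb upstream, 4 IDR summits were counted, 1 of them among the 6, with signals from 102.5 to 223.7.

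**Figure D1:**
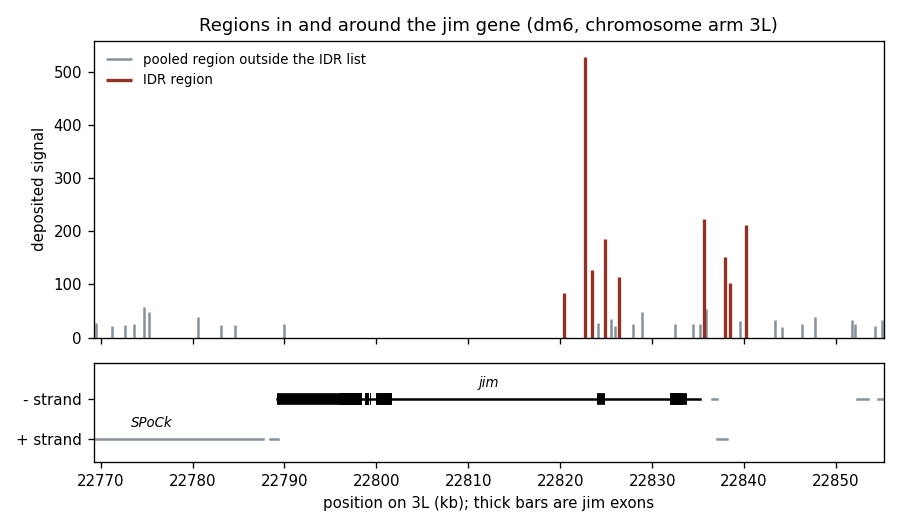
Regions of the pooled list in and around jim on 3L (horizontal axis, kb, dm6), with the deposited signal as the height of each line. Red lines are IDR regions, grey lines are other pooled regions, and the lower panel shows protein-coding genes by strand with jim exons as thick bars. The tallest line, at a signal of 529.5, stands in an intron of jim.

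Behind jim, an intronic peak of osp (FBgn0003016, 2L, 14685732 to 14685899) had a signal of 528.0, 3521 bp from the nearest TSS. A peak 426 bp from a TSS of Pka-R2 (FBgn0022382, 2R, 10025504 to 10025723), a regulatory subunit of protein kinase A, had a signal of 491.5. A peak between genes, 429 bp from a TSS of ph-d (FBgn0004860, X, 2123599 to 2123804), a Polycomb repressive complex subunit, had a signal of 360.2. Peaks in introns of aralar1 (FBgn0028646, 3R, 30450449 to 30450595), a mitochondrial carrier, and Rho1 (FBgn0014020, 2R, 16104320 to 16104467), a small GTPase, reached 345.0 and 343.3. A peak 117 bp from a TSS of CG14100 (FBgn0036889, 3L, 19590530 to 19590693) had a signal of 373.6 and ranked 21 in replicate 1, with no region of replicate 3 at its summit. The nearest TSS of the remaining 3 of the 10 strongest peaks belonged to noncoding RNAs. These were lncRNA:CR45437 (FBgn0266986, 3L, 16195575 to 16195697, signal 358.2), an RNA without a symbol inside CG5953 (2L, 16526085 to 16526217, signal 350.0) and lncRNA:CR46090 inside pnt, which encodes an ETS factor (3R, 23334189 to 23334324, signal 337.8). Of these 10 peaks, 9 had a region of each replicate at the summit, ranked 1 to 49 in replicate 1 and 1 to 29 in replicate 3.

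The protein-coding gene with the most IDR summits was sbb. The gene body and 2 kb upstream of sbb, a transcriptional corepressor gene (FBgn0285917, 2R, 18278198 to 18357296), held 13 IDR summits, and tara (FBgn0040071, 3R, 16225651 to 16260329) held 9. InR, which encodes the insulin receptor (FBgn0283499, 3R, 21570248 to 21619321), Tlk, which encodes a protein kinase (FBgn0283657, X, 3720007 to 3789770), and Mur2B (FBgn0025390, X, 1523554 to 1668788) held 7 each. The span of Mur2B contains that of br (X, 1575132 to 1664869), an ecdysone-induced transcription factor gene with 5 summits. These counts were not adjusted for gene length, which was 79.1 kb for sbb and 34.7 kb for tara.

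Of the 1476 strongest regions of replicate 1, 743 (50.3%) were found in the 1476 strongest of replicate 3 and 1203 (81.5%) in its whole list. In the other direction these were 720 (48.8%) and 1244 (84.3%). Of the 1476 IDR peaks, 739 (50.1%, 47.5% to 52.7%) had their summit in the 1476 strongest regions of both replicates. Replicate 1 held 1044 (70.7%, 68.3% to 73.0%) and replicate 3 held 1094 (74.1%, 71.8% to 76.3%), while 77 (5.22%) lay in neither. In the whole lists of 30000 regions, 1367 (92.6%, 91.2% to 93.9%) were found in both, where the whole lists covered 4.70% of the arms in replicate 1 and 5.82% in replicate 3. Across these 1367 peaks, the replicate signals had a Spearman correlation of 0.251 (bootstrap interval 0.195 to 0.301) and a Pearson r of 0.356 on log2 values. Peaks are not independent replicates, and the IDR list holds only the strongest regions, which narrows the range of signal. Over all 7752 pooled regions found in both replicates the Spearman correlation was 0.533.

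IDR peaks lay at promoters more often than weaker regions did. A TSS stood within 500 bp of 836 of 1476 summits (56.6%, 54.1% to 59.2%), against 6630 of 28524 other pooled regions (23.2%) and 13.5% of random positions. The odds ratio over the other pooled regions was 4.31 (3.88 to 4.80, Fisher's exact p = 3.83e-157). At ranks 1477 to 3000, just below the IDR list, the share was 53.2% (50.7% to 55.7%), so the contrast came from weaker regions. The median distance to the nearest TSS was 294 bp for IDR peaks and 2044 bp for the others. Outside promoters, 466 IDR peaks (31.6%) lay in introns, 123 (8.33%) between genes, 21 (1.42%) in 5 prime UTRs, 13 (0.881%) in noncoding exons, 11 (0.745%) in 3 prime UTRs and 6 (0.407%) in coding sequence. Coding sequence took 8.49% of the other pooled regions, an odds ratio of 0.0440 (0.0197 to 0.0982, Fisher's exact adjusted p = 2.09e-45). Replicate 1 alone gave a promoter share of 59.4% against 25.4%, and replicate 3 alone 53.4% against 21.1%. Promoter and distal IDR peaks had median signals of 85.4 and 87.1, a log2 difference of -0.03 (-0.09 to 0.04, permutation p = 0.427), which did not pass the test.

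**Figure D2:**
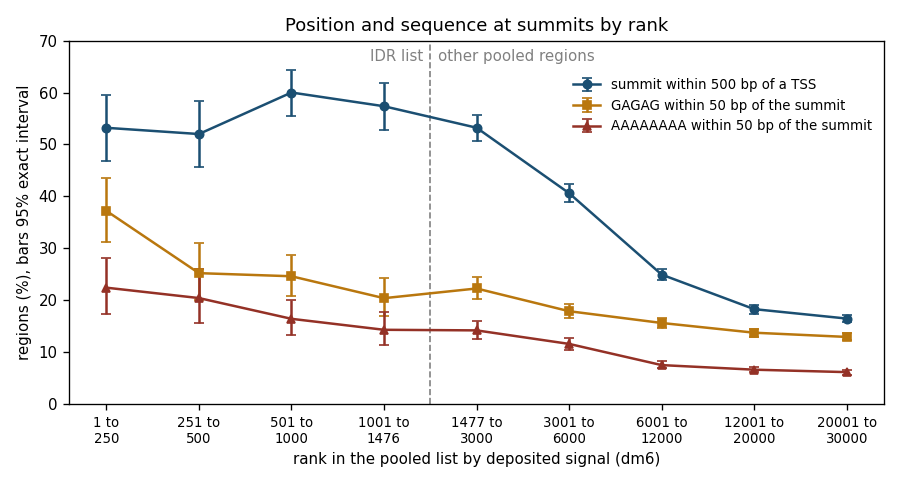
Percent of regions (vertical axis) with a TSS within 500 bp of the summit, with GAGAG, or with AAAAAAAA within 50 bp of the summit, by rank in the pooled list (horizontal axis, unequal bins). Bars are 95% exact intervals and the dashed line ends the IDR list. Promoter shares stay between 52.0% and 60.0% over the IDR list, stand at 53.2% at ranks 1477 to 3000 and reach 16.5% in the weakest bin.

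The X chromosome carried 239 of the IDR peaks (16.2%, 14.3% to 18.2%) against 12.8% of the other pooled regions, an odds ratio of 1.32 (1.14 to 1.52, Fisher's exact p = 0.000212). Arms 2L, 2R, 3L and 3R carried 265, 307, 328 and 337, and densities ran from 10.2 per Mb on X to 12.1 per Mb on 2R. Against the share of X in arm length, 17.6%, the X odds ratio was 0.904 (0.787 to 1.04, Fisher's exact p = 0.168). Larvae of both sexes together carry fewer copies of X than of the autosomes. Arm length ignores this, while the other pooled regions come from the same larvae, so the 2 backgrounds are not equal tests of direction. No IDR peak lay on chromosome 4, where 295 of the other pooled regions (1.03%) lay and 15.3 peaks would have matched that share (Fisher's exact p = 5.08e-07). A count of 0 allows a share of up to 0.203%, taken as 3 of 1476 regions. Among the 1476 strongest regions of each replicate alone, chromosome 4 held 1 in replicate 1 and 5 (0.339%) in replicate 3.

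Genes of the lists for growth control, disc patterning, the Polycomb and trithorax group, ribosomal proteins and heat shock proteins carried IDR peaks at their promoters more often than other genes. Of 13945 protein-coding genes, 970 (6.96%, 6.5% to 7.39%) had an IDR summit within 500 bp of a TSS. Of the 26 lists, 5 were higher than other genes and 2 were lower at the threshold, and 19 did not pass.

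The insulin and TOR growth control list stood highest, with 7 of 19 members (36.8%), an odds ratio of 7.85 (3.08 to 20, Fisher's exact adjusted p = 0.00316). Its members included Thor (FBgn0261560, 2L, 3478375 to 3478634, signal 145.4), the translational repressor 4E-BP, and foxo (FBgn0038197, 3R, 14056786 to 14057045, signal 99.8), the forkhead factor of insulin signalling. InR (3R, 21619175 to 21619434, signal 96.9) and Sesn (FBgn0034897, 2R, 23713798 to 23714057, signal 90.1), a stress-induced inhibitor of TOR, also belonged to it. In replicate 3 alone 5 of 19 members were bound (26.3%) and the odds ratio was 5.13 (1.84 to 14.3, exact adjusted p = 0.0331, range over the alternatives 0.0014 to 0.0874), below that of disc patterning. In replicate 1 alone 7 were bound.

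Imaginal disc patterning had 9 of 42 members (21.4%), an odds ratio of 3.67 (1.75 to 7.69, exact adjusted p = 0.0108). In replicate 3 alone 12 of 42 were bound (28.6%), an odds ratio of 5.78 (2.95 to 11.3, exact adjusted p = 0.000262). The highest peak of the list stood 241 bp from a TSS of bi (FBgn0000179, X, 4426857 to 4426987, signal 283.2), a T-box factor. It was followed by vn (FBgn0003984, 3L, 5845490 to 5845749, signal 126.3), a ligand of the EGF receptor, by Egfr itself (FBgn0003731, 2R, 21546349 to 21546608, signal 95.7) and by salr (FBgn0000287, 2L, 11358514 to 11358773, signal 94.3), a zinc finger factor of the wing. The Polycomb and trithorax group had 6 of 22 members (27.3%), an odds ratio of 5.04 (1.97 to 12.9, exact adjusted p = 0.0138). Besides ph-d these were led by ph-p (FBgn0004861, X, 2137075 to 2137222, signal 290.7), Psc (FBgn0005624, 2R, 12980638 to 12980897, signal 234.6) and Su(z)2 (FBgn0265623, 2R, 12996401 to 12996660, signal 126.0), which are 2 pairs of neighbouring Polycomb genes. With 1 TSS per gene the disc patterning list no longer passed (exact adjusted p = 0.121, range over the alternatives 7.65e-06 to 0.374). With the 2952 strongest pooled regions the Polycomb and trithorax list did not (exact adjusted p = 0.0501, range 0.00133 to 0.281).

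Ribosomal proteins had 14 of 85 members (16.5%), an odds ratio of 2.66 (1.49 to 4.73, exact adjusted p = 0.0108), led by RpS29 (FBgn0261599, 3R, 9777910 to 9778169, signal 160.2), RpL34b (FBgn0037686, 3R, 9401160 to 9401419, signal 132.5) and RpS4 (FBgn0011284, 3L, 13041549 to 13041808, signal 110.1). Of the 14, 6 were bound in both replicates taken alone. The list passed in 5 of 9 alternatives, and not with a window of 1000 bp, over gene bodies or with the 738 strongest IDR peaks (adjusted p from 0.000131 to 0.444 over the alternatives). Heat shock proteins had 5 of 21 members (23.8%), an odds ratio of 4.19 (1.53 to 11.5, exact adjusted p = 0.0479). They were Hsp26 (FBgn0001225, 3L, 9377202 to 9377461, signal 119.1), Hsp27 (FBgn0001226, 3L, 9383813 to 9384072, signal 117.1), stv (FBgn0086708, 3L, 13477434 to 13477693, signal 109.0), a chaperone cofactor, the noncoding RNA gene lncRNA:Hsromega (FBgn0001234, 3R, 21296525 to 21296784, signal 95.3) and Hsc70-4, the constitutive Hsp70 cognate, which was named after its values were seen. This last list passed in neither replicate alone, with an odds ratio of 3.37 in replicate 3 (exact adjusted p = 0.129) and 2.17 (0.638 to 7.37) in replicate 1 (adjusted p = 0.346). It passed in 3 of 9 alternatives (adjusted p from 0.0248 to 0.346), and not with 1 TSS per gene (exact adjusted p = 0.121). Against only the genes with any pooled region at a TSS, none of 25 lists passed by Fisher's exact test with adjustment, and 4 had an unadjusted p under 0.05.

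Cuticle proteins and replication-dependent histones were the 2 lists below other genes. No IDR peak stood at any of 123 cuticle protein genes (exact adjusted p = 0.00316) or of 111 histone genes (adjusted p = 0.00469). Of the cuticle genes, 25 (20.3%) had a pooled region of any rank at a TSS, against 42.8% of protein-coding genes. Of the histone genes 0 had one. They stand in a tandem array of near-identical copies, and how reads with several placements were handled is not given in the sources used here, so their count does not measure occupancy. With the 738 strongest IDR peaks neither list passed (exact adjusted p = 0.100 and 0.128).

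Steroid hormone and tissue lists did not pass in the main comparison. The ecdysone response had 5 of 22 members (22.7%, exact adjusted p = 0.0512), with peaks at Eip75B (signal 139.5) and EcR (signal 131.1), the ecdysone receptor gene. Counted over gene bodies and 2 kb upstream, 13 of its 22 genes carried an IDR summit (59.1%), against 10.7% of other genes (Fisher's exact adjusted p = 1.26e-06). That count rises with gene length, and Eip75B, br and EcR span 113.7, 89.7 and 81.2 kb. The list passed in 5 of 9 alternatives, with adjusted p from 1.26e-06 to 0.600. The highest came with 1 TSS per gene, where 2 of its 22 members were bound (9.09%, against 5.78% of other genes). The trachea and Notch lists each passed in 1 of 9. The trachea list had 3 of 9 (33.3%, exact adjusted p = 0.0594), with bnl (signal 100), an FGF ligand gene, and sima (signal 77.1), the HIF homologue. Insulator and architectural proteins had 3 of 14, with Chro (signal 160.6) and BEAF-32 (signal 81.8), fat body 3 of 18, with Lsd-2 (signal 100.1) and bmm (signal 95), and innate immunity 3 of 26, with imd (signal 123.7) and Tl (signal 112.5). The circadian clock list had 2 of 11, with vri (signal 104.5) and dco (signal 71.5), germline 2 of 13, with pum (signal 69.0) and tud (signal 66.6), and glia 2 of 13, with moody (signal 78.6) and Gs2 (signal 71.9). The Notch pathway and E(spl) list had 2 of 20, with E(spl)mbeta-HLH (signal 101.3) and mam (signal 81.9), midgut 2 of 22, with cad (signal 99.6) and Myo31DF (signal 98.5), and muscle 2 of 27, with Mef2 (signal 151.9) and Msp300 (signal 76.5). The respiratory chain had 2 of 80 (2.5%, exact adjusted p = 0.359), namely COX5A (signal 73.3) and ATPsynE (signal 69.5). A single member was bound in dosage compensation (msl-1, 1 of 8), hemocyte (ush, 1 of 16), neuroblast and temporal factors (Syp, 1 of 20), cell cycle (Dp, 1 of 22), salivary glue and late larval genes (Sgs1, 1 of 22) and neuron (Fas2, 1 of 24), and 0 of 8 Hox genes were bound. These small counts moved with the replicate. Each replicate alone gave 4 of 20 for neuroblast and temporal factors, with odds ratios of 3.58 in replicate 3 and 3.26 in replicate 1 against 0.703. Insulator and architectural proteins had 1 of 14 in replicate 3 alone (odds ratio 1.10 against 3.65), and glia had 1 of 13 in each alone. Hemocyte had 0 in replicate 3 alone, salivary glue and neuron had 0 in replicate 1 alone, and the Hox genes had 1 there. Intervals on the odds ratio of these lists were wide, from 0.0453 to 13.6 for the Hox genes.

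**Figure D3:**
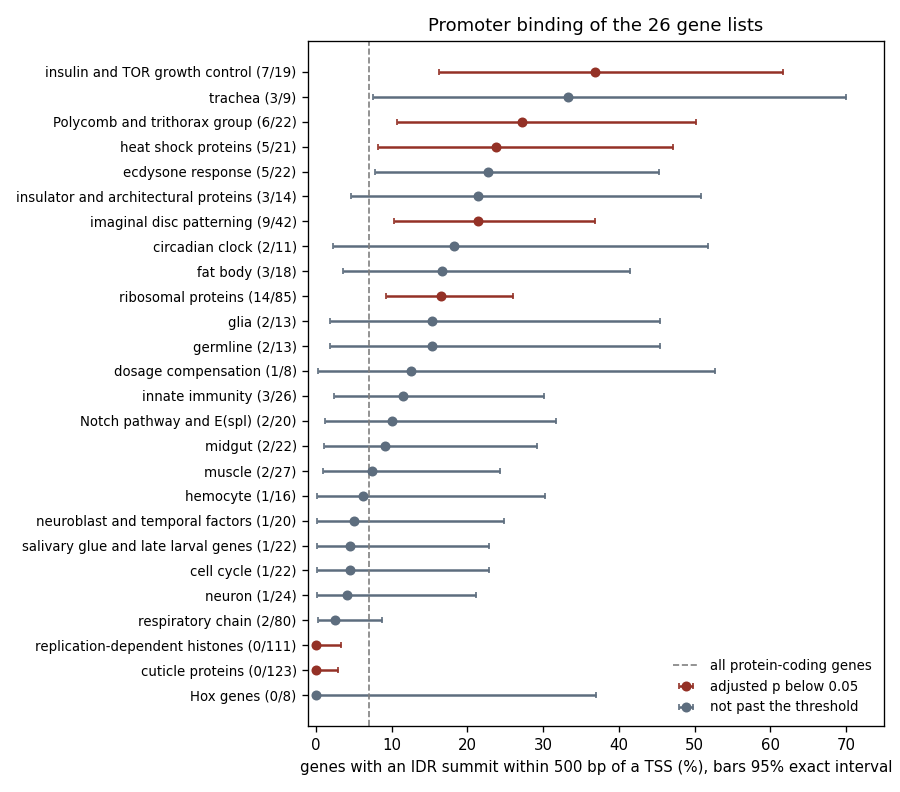
Percent of the genes of each list with an IDR summit within 500 bp of a TSS (horizontal axis), with 95% exact intervals as bars and the number of bound and listed genes beside each name. Red points passed the adjusted threshold, and the dashed line at 6.96% is the share of all protein-coding genes. Insulin and TOR growth control stands highest at 36.8%.

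Runs of A and GA repeats had the smallest adjusted p among the preset motifs. AAAAAAAA or its complement lay within 50 bp of 257 of 1476 summits (17.4%) and in 5.62% of 2952 flank windows, an odds ratio of 3.54 (2.88 to 4.35, Fisher's exact adjusted p = 1.21e-32). GAGAG, the repeat recognised by GAGA factor, lay at 376 summits (25.5%) and in 12.7% of flanks (odds ratio 2.34, 2.00 to 2.75, exact adjusted p = 3.65e-24). CACACACA was at 7.18% against 3.32% (odds ratio 2.25, exact adjusted p = 1.17e-07), the forkhead site TGTTTAC at 4.34% against 1.66% (odds ratio 2.69, adjusted p = 1.06e-06) and the DNA replication-related element TATCGATA at 1.63% against 0.373% (odds ratio 4.42, adjusted p = 0.000106). In each replicate alone these 5 sequences passed the threshold, with odds ratios for the A tract of 3.44 and 3.48.

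Of the preset motifs, 6 were less frequent at summits than in flanks. The TATA box TATAAA stood at 6.17% of summits and 12.2% of flanks (odds ratio 0.472, exact adjusted p = 7.58e-10), the homeodomain core TAATTA at 2.10% and 5.35% (odds ratio 0.379, adjusted p = 6.39e-07) and TATATATA at 0.339% and 1.49% (odds ratio 0.225, adjusted p = 0.000962). The Pho core GCCATT was at 4.67% and 7.15% (odds ratio 0.637, exact adjusted p = 0.00333), the nuclear receptor site AGGTCA at 1.42% and 2.57% (odds ratio 0.546, adjusted p = 0.0283) and the STAT site at 1.56% and 2.71% (odds ratio 0.568, adjusted p = 0.0407). In replicate 3 alone the odds ratio was 0.747 for the TATA box, 0.560 for TAATTA and 0.344 for TATATATA. In replicate 1 alone it was 0.332 for the TATA box, 0.237 for TAATTA and 0.145 for TATATATA. Summit windows held 45.6% G and C and flanks 42.5%. Against random windows matched on G and C content, the TATA box and TATATATA no longer passed (exact adjusted p = 0.183 and 0.407). In windows of 25 bp to each side the DNA replication-related element, CACACACA, TATATATA, AGGTCA and the STAT site did not pass, at distal peaks the first, AGGTCA and the STAT site did not, and with flanks at 500 bp GCCATT and AGGTCA did not. With the 738 strongest peaks TATCGATA and AGGTCA did not pass, and in replicate 3 alone the STAT site did not. The remaining 12 motifs did not pass in the main comparison, among them CTCF (0.678% against 0.237%, exact adjusted p = 0.0701) and Zelda (0.610% against 0.644%, adjusted p = 1). In replicate 3 alone CTCF stood at 0.407% of summits and Zelda at 0.203%, and in replicate 1 alone at 0.678% each. Over 10 alternatives CAGCTG passed in 4, CTCF and M1BP in 3 each and AP-1 in 1, each as higher at summits. Su(H) passed in 3 and GATA in 1, both as lower at summits.

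**Figure D4:**
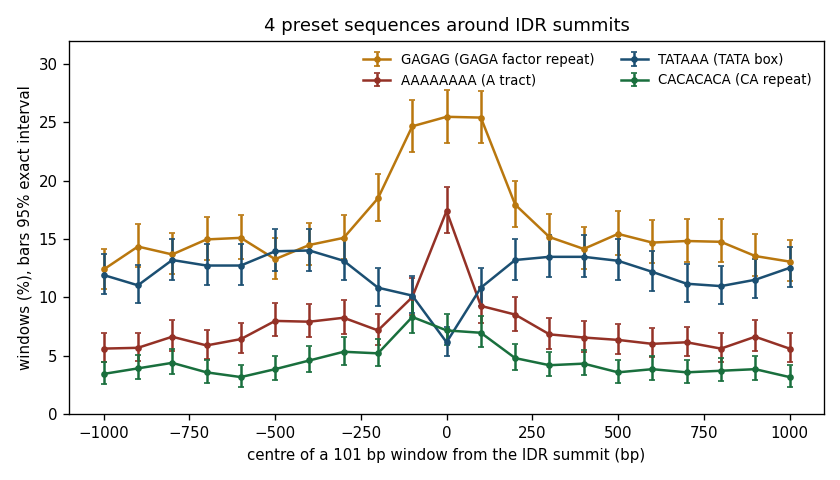
Percent of windows of 50 bp to each side of a centre (vertical axis) that hold each of 4 preset sequences on either strand, by distance of the window centre from the IDR summit (horizontal axis, bp). Bars are 95% exact intervals over 1476 peaks. The A tract peaks at 17.4% in the summit window and falls to 10% and 9.28% in the next windows, while GAGAG spreads over 3 windows at 24.7%, 25.5% and 25.4%.

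Runs of A led the search over 6-mers. Of 2080 6-mers, 288 were higher and 360 lower at summits at the threshold, and in replicate 3 alone 430 passed in place of 648. The 5 higher ones with the smallest adjusted p were AAAAAA (35.9% of summits against 19.0% of flanks, Fisher's exact adjusted p = 2.71e-30), AAAAAG (27.4% against 15.6%), AGAGAG (13.9% against 5.56%), AAACAA (29.5% against 17.5%) and CAAAAA (32% against 19.9%). The 5 lower ones were AATTTA (5.76% against 14.6%, exact adjusted p = 7.24e-17), AAGATT (1.9% against 6.61%), ATCCTG (0.407% against 3.52%), AATTAT (5.35% against 11.6%) and ATTTAA (7.72% against 14.8%). In replicate 3 alone the odds ratios of AAGATT, ATCCTG and AATTAT were 0.419, 0.177 and 0.673, against 0.273, 0.112 and 0.430. The 6-mers overlap one another, so these counts are not counts of separate sites. AATTAT and ATTTAA no longer passed against windows matched on G and C content (exact adjusted p = 0.109 and 0.353). Coding sequence over 500 bp from a TSS held 0.407% of IDR summits and 13.8% of random positions. The control windows of motifs and 6-mers were not matched on coding content, so its part in these contrasts was not tested.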

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

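Of the tests in this part, those on genes with any pooled region at a TSS were specified before their results were seen. The tests on the A tract and on jim were chosen after the patterns had been seen.

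The dm3 IDR list held 7 regions outside the 6 arms, above the limit of 3 that a count of 0 allows. These lay on unplaced sequence (5 on Uextra) and on heterochromatin sequences (1 on 2RHet and 1 on 3RHet). The dm6 IDR list held 0 outside the arms. The whole dm6 pooled list held 0 there too, against 206 in the dm3 pooled list, so 7 and 0 are not a like contrast. The 5 on Uextra ranked 54, 96, 74, 98 and 304 in replicate 3, and the others 324 and 1038. In replicate 1 the 7 ranked 836 or lower, with 1 not found there. Under their dm3 coordinates they enter only the dm3 counts and dm3 replicate overlap. No coordinate was converted, so whether the same sequence lies on an arm of dm6 is not known.

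The first pattern weighed was the A tract at IDR summits. The tables argue against base composition as the whole cause, since the odds ratio was 4.58 (3.45 to 6.07) against windows of equal G and C content. The 10000 weakest pooled regions had an odds ratio of 1.05 (0.949 to 1.16) against their own flanks. By its label the pooled list holds peaks and background, so this does not show whether all called peaks share the tract. Regions below the IDR list held the tract too, at 14.2% for ranks 1477 to 3000 and 11.6% for ranks 3001 to 6000. Promoter sequence was not the whole cause either, as distal summits gave 3.92 (2.96 to 5.19). None of these control windows were matched on coding content, so its part was not tested. Contact of Jim with A tracts remains a hypothesis that was not tested. A preference of the shearing or of the antibody for strongly open sites was not tested either, because the values of the control were not used here.

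The second pattern was the cluster of peaks in jim. A tagged line can hold extra copies of the tagged region, which could raise all regions there. The pooled regions outside the IDR list had 0.979 times the density of the arms (0.469 to 1.80) over jim and its 2 kb upstream, a test that leaves out any region a rise had moved into the IDR list. Other pooled regions between the intronic peaks had signals of 27.9, 34.3 and 21.0 near the peak of 529.5, where the median of the pooled list was 26.4. For a copied segment that spans these regions, the values argue against a uniform rise as the whole cause of that height. The size of such a segment is not given. No pooled region lay between 22790069 and 22820294, but that stretch has no measured baseline, so it decides nothing. Each list derives from an alignment and a control, but whether that control came from the same line is not stated here. For the number of peaks, extra copies and binding of the tagged protein to its own gene therefore cannot be told apart. No biological explanation was tested.

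The third pattern was the excess of 5 gene lists at promoters. Part of it may come from promoters at which regions of any strength are called, as at open chromatin. Among genes with a pooled region at a TSS the odds ratio was 5.19 (1.81 to 14.8) for insulin and TOR growth control. It was 2.82 (1.04 to 7.65) for the Polycomb and trithorax group and 6.47 (1.73 to 24.1) for heat shock proteins. Among all genes these were 7.85, 5.04 and 4.19. The 3 unadjusted intervals lay above 1, but Fisher's exact adjusted p was 0.0874, 0.281 and 0.0994. This comparison takes pooled regions of any rank, background included, and does not match promoters on strength. Of all protein-coding genes, 42.8% had a pooled region at a TSS. The share was 73.7% for insulin and TOR growth control and 77.3% for the Polycomb and trithorax group. For both the explanation stays open. For heat shock proteins the share was 42.9% (21.8% to 65.98%), and their odds ratio was higher among such genes. Those values argue against the explanation for that list, though its interval is wide and the adjusted threshold was not passed. The odds ratio was 2.03 (0.935 to 4.39) for imaginal disc patterning and 1.51 (0.83 to 2.75) for ribosomal proteins, against 3.67 and 2.66. Of the members of these lists, 76.2% and 72.9% had a pooled region at a TSS, and the explanation stays open there too. None of the 5 passed the adjusted threshold in that comparison, with 14, 17, 9, 32 and 62 genes in the respective lists and about 16.2% of the other genes bound in place of 6.92%; no biological explanation was tested.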

How the results depend on the processing

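The 2N strongest pooled regions were an alternative chosen after seeing the data, and all others were planned. The 1476 strongest pooled regions are the IDR list itself and are left out of the counts here. The promoter odds ratio stayed above 1 and past the threshold in each alternative, from 3.74 to 8.34. The share of IDR peaks found in both replicates was 78.0% with 2952 regions per replicate, 92.6% with whole lists and 78.3% over the 738 strongest IDR peaks, as longer lists or stronger peaks make overlap easier. The Spearman correlation of the replicate signals was 0.533 over all pooled regions found in both. The X odds ratio was 0.904 against arm length, which ignores the number of X copies, and above 1 in the other settings. The log2 signal difference between promoter and distal peaks was 0.00577 with a TSS window of 1000 bp (permutation p = 0.842) and 0.0464 with the 2N strongest regions (permutation p = 0.0501), and the cause was not tested. The number of gene lists past the threshold was 5 to 8 in the other settings and 0 among genes with a pooled region at a TSS, where lists were shorter and the histone list gave no value. The number of motifs was 7 with a summit window of 25 bp on each side, and that of 6-mers was 332 there, 284 at distal peaks and 345 over the 738 strongest peaks, where fewer bases or peaks entered. In 1 replicate alone, the promoter odds ratio was 4.29 to 4.30, the X odds ratio 1.32 to 1.5, the number of lists 6 to 7, of motifs 11 to 12, of 6-mers 430 (replicate 3) to 773 (replicate 1), and of peaks in jim 5 to 6, and the log2 signal difference was -0.04 to -0.02. Of single named lists, motifs and 6-mers, 18 of 62, 15 of 110 and 2 of 100 comparisons with the alternatives lost their call and 0 turned. The A tract, GAGA repeat, forkhead and homeodomain sequences passed in all 10 alternatives. Read depth is unknown, so whether it limits the weaker regions was not assessed. No paired analysis was possible because there is a single group.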

Other observations

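All comparisons in this part were chosen after seeing the data, and no explanation of them was tested.

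Distal and promoter peaks differed in sequence. The A tract stood at 23.3% of 640 distal summits and 12.9% of 836 promoter summits (odds ratio 0.489 for promoter over distal, 0.372 to 0.642, Fisher's exact adjusted p = 5.95e-06), and GAGAG at 32% and 20.5% (odds ratio 0.546, 0.431 to 0.691, adjusted p = 6.07e-06). The DNA replication-related element went the other way, at 0.469% and 2.51% (odds ratio 5.47, 1.62 to 18.4, exact adjusted p = 0.0119). Of all 1476 summits, 566 (38.3%) held the A tract or GAGAG, and 67 (4.54%) held both, where 4.44% would hold both if the sequences were independent (odds ratio 1.04, Fisher's exact p = 0.813).

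Both sequences were commonest at the strongest regions. GAGAG fell from 37.2% (31.2% to 43.5%) in the 250 strongest pooled regions to 20.4% (16.8% to 24.3%) in the weakest 476 of the IDR list, and the A tract from 22.4% (17.4% to 28.1%) to 14.3% (11.3% to 17.8%). Over the same ranks the promoter share went from 53.2% (46.8% to 59.5%) to 57.4% (52.8% to 61.8%). At ranks 1477 to 3000, just below the IDR list, the A tract stood at 14.2% and GAGAG at 22.2%. At ranks 20001 to 30000 the A tract stood at 6.13% and GAGAG at 12.9%.

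Some IDR peaks had no counterpart in 1 replicate. No region of the whole list of replicate 3 overlapped 49 IDR peaks, 8 of them among the 250 strongest, and no region of replicate 1 overlapped 6. Of the 49, 42 (85.7%) lay within 500 bp of a TSS, against 55.6% of the other IDR peaks (odds ratio 4.78, 2.13 to 10.7, Fisher's exact p = 1.35e-05). Of the 6 missing from replicate 1, 1 did (16.7%, against 56.8% of the others, odds ratio 0.152, Fisher's exact p = 0.0911). The strongest of the 49 missing from replicate 3, at CG14100, held rank 4 in the pooled list and rank 21 in replicate 1.

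The replicate lists differed in their chromosomes and base content. X held 4509 of 30000 regions (15%) in replicate 1 and 3283 of the 29999 regions on the arms (10.9%) in replicate 3, an odds ratio of 1.44 (1.37 to 1.51, Fisher's exact p = 3.10e-50), and chromosome 4 held 236 and 379. Summit windows of the 1476 strongest regions held 47.6% G and C in replicate 1 and 43.0% in replicate 3, with flanks at 42.9% and 42.3%.

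Among genes that do not encode proteins, 102 of 3261 ncRNA genes (3.13%, 2.56% to 3.78%) had an IDR summit within 500 bp of a TSS, 6 of 290 tRNA genes (2.07%, 0.763% to 4.45%), 4 of 269 snoRNA genes (1.49%) and 3 of 32 snRNA genes (9.38%, 1.98% to 25%), against 6.96% (6.5% to 7.39%) of protein-coding genes.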
